A study of Phaseolus vulgaris with 12 samples.

How the data were processed

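Transcript levels were measured by RNA sequencing in true leaves of 2 varieties of common bean (Phaseolus vulgaris), 093 and 120, which the study's design text calls cold-sensitive and cold-tolerant. Plants stayed at 4 °C for 3 days in an incubator or without cold on a culture rack, with 12 h of light per day in both. Cold and place thus cannot be told apart. The 12 libraries form 4 groups of 3: 093 control, 093 cold, 120 control and 120 cold. The design text gives 3 pots per variety and treatment with 4 seeds per pot. The labels do not say that the 3 libraries of a group came from separate pots or plants, so p-values measure the spread between these libraries, which may be technical. The sources used here give no time of day of sampling.

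Per the labels, total RNA was extracted with Trizol, mRNA was selected with oligo(dT) beads, and stranded libraries made with dUTP in the second strand were sequenced as read pairs on an Illumina NovaSeq. Per the submitters' processing notes, the authors' tools were cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d. The notes also name DESeq2 and edgeR, not used here, without version or role. The deposited values are FPKM (fragments scaled by transcript length and mapped fragments) calculated by the authors, with 1 column per library, per the file headers. Read counts were not analysed here. The table gives no coordinates, and the sources used here give no genome build.

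The table holds 22542 loci with gene descriptions, GO terms and KEGG pathways. StringTie numbers (MSTRG) identify 12984 of them, 578 have no gene name, 307 carry more than 1 gene name, and 325 share a gene name with another locus. A locus is named below by its Phvul gene name where that name is its own, and otherwise by its MSTRG number. A table of RefSeq gene names was not used because 0 of its locus tags matched the gene names. FPKM summed to between 313320 and 350100 per library, and between 12091 and 13357 loci reached 1 FPKM. Between 3457 and 4835 loci were listed at 0 in a library. Total read numbers are unknown, so no counting interval is given. The spacing of the lowest values put the relative depth of the libraries between 1.00 and 1.40. That of 120 control library 3 came out as 1.40 by way of 093 cold library 2 and as 2.78 when set directly against 093 cold library 1, so it is open by a factor.

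The comparisons, tests, thresholds, gene lists and rule for naming genes were fixed before the data were examined. Loci with at least 1 FPKM in at least 3 of the 12 libraries were tested, which left 14716 loci, 11824 of them with a description. A linear model on log2(FPKM + 1) with 1 mean per group was fitted to all 12 libraries in R 4.3.3 with limma 3.58.1, with a trend of variance on mean level. There were 5 contrasts: cold against control in 093, cold against control in 120, the difference of these responses (120 minus 093), 120 against 093 without cold, and 120 against 093 under cold. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast. A locus was called at an adjusted p under 0.05 and an absolute log2 change of at least 1. Adjusted p-values of loci below are from limma. The words rose and fell are used for called loci. Values are mean FPKM ± SD of a group's 3 libraries, and log2 changes and ranks are the model's.

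In each cold contrast, the difference of the responses and the comparison without cold, the 5 called loci with the largest rise and the 5 with the largest fall were eligible to be named. They needed an informative description and, outside the difference of the responses, libraries that did not overlap between the groups. From each gene list with a called member in either cold contrast, the 2 called members with the largest mean absolute log2 change over both cold contrasts were eligible too. Any other locus named below is said to have been chosen after its values were seen.

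The 40 gene lists were written as words to be matched in the gene descriptions. They were CBF/DREB factors, cold-regulated, dehydrin and LEA proteins, galactinol and raffinose synthesis, starch synthesis and breakdown, sucrose and trehalose metabolism, light-harvesting antenna proteins, photosystem I and II subunits, Calvin cycle enzymes, chlorophyll and tetrapyrrole synthesis, early light-induced proteins, heat shock proteins and chaperones, heat shock transcription factors, antioxidant enzymes, glutathione S-transferases, class III peroxidases, phenylpropanoid and flavonoid synthesis, and abscisic acid, jasmonate and ethylene synthesis and signalling. The others were auxin-responsive genes, gibberellin and cytokinin metabolism and signalling, circadian clock, calcium sensors and kinases, WRKY, NAC, ethylene-responsive AP2/ERF and MYB factors, fatty acid desaturases, lipid transfer proteins, cell wall loosening, cell division, cytosolic and plastid ribosomal proteins, aquaporins, pathogenesis-related proteins and chitinases, NBS-LRR disease resistance genes, seed storage and cotyledon proteins, nodule and root proteins, and flower and pollen proteins. The last 3 stand for tissues other than leaf. Lists with at least 5 tested members, 37 in all, were tested with limma's camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with a correlation estimated from the data was run beside it. Members called were counted over all loci tested and adjusted over the list alone.

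GO and KEGG terms with 10 to 500 tested members, 1006 in all, were tested for an excess of called loci by direction with a one-sided Fisher exact test against all tested loci. That test treats loci as independent, so its p-values may be too small where members vary together. The model was checked on simulated data with 12 libraries, 14716 loci and 200 changed loci. In the cold contrast of 093 it recovered 90% of changes of 1.5 log2 and 98% of changes of 3 log2 with 3 false calls. For the difference of the responses it recovered 76% and 95% with 6 false calls. The simulated noise was normal and independent between loci, with 1 spread per locus for all groups. The real groups had median SDs from 0.098 log2 in 093 cold to 0.227 in 120 cold. Changes were put into 093 cold alone, at loci with a mean log2 value above 1. These figures thus do not cover correlated loci, unequal spreads or changes in many loci.

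The alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 FPKM, scaling to equal totals (TPM), median-ratio size factors, quantile normalization, no variance trend, library weights, a fit of only the groups compared, no minimum change, the replicate number as a block, leaving out loci without a gene name, leaving out each library in turn, and the estimated correlation for the lists. Leaving out 093 control library 3 and 120 cold library 3 together was chosen after seeing the data. Terms of the cold contrasts were repeated with no minimum change and with quantile normalization. The share of all tested loci whose groups do not overlap and the count of lists with fewer rises under other scalings were added after the results were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.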

Results

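On log2(FPKM + 1), ribonuclease 1 (Phvul.002G170800), an RNA-degrading enzyme, had the largest rise of described loci in both varieties. It rose from 1.36 ± 0.361 to 1303 ± 379.7 FPKM in 093. In 120 it rose from 0.763 ± 0.0802 to 1536 ± 299.7 FPKM (n = 3 libraries per group throughout). In 093 the other large rises were a B12D protein (Phvul.001G258900), from 0.255 ± 0.0480 to 347 ± 21.7 FPKM, and a laccase (Phvul.008G112200), from 0.0908 ± 0.0357 to 271 ± 20.7 FPKM. An AMP-dependent synthetase (Phvul.006G079500) rose from 0.0746 ± 0.0581 to 167 ± 6.37 FPKM, and a PAR1 protein (Phvul.010G006000) rose from 0.396 ± 0.276 to 171 ± 6.58 FPKM. The largest falls were a glycosyl hydrolase (Phvul.001G219800), from 1093 ± 220.2 to 9.89 ± 0.674 FPKM, and a xyloglucan endotransglucosylase/hydrolase (XTH6, MSTRG.11313), which remodels cell walls, from 508 ± 142 to 5.52 ± 0.312 FPKM. A UbiA prenyltransferase (Phvul.002G210750) fell from 137 ± 77.8 to 1.11 ± 0.133 FPKM. An Ntn hydrolase (Phvul.001G025000) fell from 386 ± 72.9 to 7.64 ± 0.518 FPKM, and a peptidase M28 locus that carries 2 gene names (MSTRG.995) fell from 64.4 ± 17.1 to 0.564 ± 0.0634 FPKM.

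Of the 14716 loci tested in 093, limma called 7096 (48.2%), 4857 higher and 2239 lower under cold. The log2 change of ribonuclease 1 was 9.08 (SE 0.221, adjusted p = 1.2e-10), with every cold library above every control library. Over all tested loci, the libraries of the groups did not overlap for 78.3%, where chance gives 10%. The median log2 change of all tested loci was 0.43, so more calls were higher (68.4%) with the deposited scaling. Median-ratio scaling moved that median by -0.41 and gave 50.1% higher calls, 3377 against 3362. Quantile normalization moved it by -0.43 and gave 49.0%, 3343 against 3480. Both scalings set the median change near 0, so the balance of calls under them follows from the scaling. Here and in the other contrasts it does not test an excess of either direction. A pseudocount of 0.1 moved it by 0.11.

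In 120 the rises beside ribonuclease 1 were led by a GRAM domain protein (Phvul.001G087100), from 1.18 ± 0.254 to 823 ± 279.9 FPKM. In 093 control this locus stood at 0.922, 1.21 and 33.8 FPKM. The PAR1 protein (Phvul.010G006000) rose from 0.486 ± 0.186 to 485 ± 118 FPKM, the B12D protein (Phvul.001G258900) from 0.282 ± 0.241 to 312 ± 34.7 FPKM and the laccase (Phvul.008G112200) from 0.0643 ± 0.0275 to 262 ± 56.0 FPKM. The glycosyl hydrolase (Phvul.001G219800) fell from 1191 ± 128 to 2.73 ± 1.91 FPKM, and a pectin methylesterase inhibitor (Phvul.002G318500) fell from 575 ± 29.7 to 2.77 ± 0.777 FPKM. The Ntn hydrolase (Phvul.001G025000) fell from 918 ± 159.8 to 6.53 ± 1.57 FPKM. The water channel PIP2;4 (Phvul.011G079300) fell from 579 ± 74.8 to 4.85 ± 0.892 FPKM, and asparagine synthase 1 (MSTRG.9850) fell from 4854 ± 117 to 72.2 ± 71.7 FPKM.

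In 120, limma called 6825 of 14716 loci (46.4%), 4092 higher and 2733 lower under cold. Ribonuclease 1 had a log2 change of 9.75 (SE 0.221, adjusted p = 7.4e-11) and was higher in 3 of 3 cold libraries. The groups did not overlap for 72.8% of all tested loci, where chance gives 10%. The median log2 change of all tested loci was 0.18, and 60.0% of calls were higher. Quantile normalization moved the median by -0.22 and gave 49.4% higher calls, 3297 against 3382. Median-ratio scaling moved it by -0.17 and gave 52.1%.

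Most of the loci called in both varieties moved the same way. Of these, 3298 rose in both, where 1351 would be shared by independent sets, and 1628 fell in both, where 416 would be. Opposite directions were called for 36 loci. The log2 changes correlated across loci (r = 0.82, rho = 0.82), with loci not being independent replicates, and had the same sign for 82.2% of loci. The contrasts share no library. Calls in 093 alone numbered 2134 and in 120 alone 1863, and the difference of the responses was itself called for 894 and 834 of these.

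**Figure D1:**
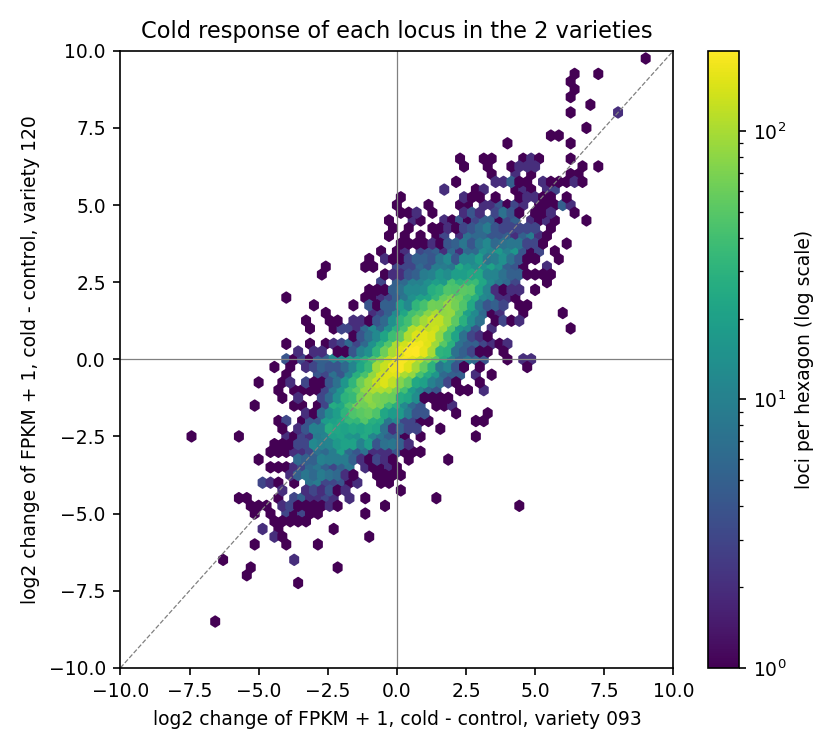
Log2 change under cold of each of the 14716 tested loci in variety 093 (x axis) against variety 120 (y axis), with shading for the number of loci per hexagon. The changes had the same sign for 82.2% of loci (r = 0.82 across loci).

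Rubisco activase (Phvul.001G234300), which keeps the carbon-fixing enzyme active, fell from 15068 ± 2936 to 2767 ± 80.6 FPKM in 093 and from 15998 ± 1736 to 1249 ± 178 FPKM in 120. In 093 its log2 change of -2.43 became -0.81 with quantile normalization and was no longer called (range over alternatives -2.96 to -0.81). Photosystem II subunit P-1 (Phvul.008G196500) fell from 891 ± 127 to 136 ± 3.62 FPKM in 093 and from 758 ± 40.9 to 73.9 ± 5.65 FPKM in 120, and subunit O-2 (Phvul.002G024000) from 49.2 ± 17.8 to 6.99 ± 0.457 FPKM in 093 and from 67.1 ± 5.70 to 4.60 ± 1.43 FPKM in 120. A locus with several gene names including chlorophyll a/b binding protein 1 (MSTRG.5016) fell from 55.1 ± 11.0 to 2.73 ± 3.39 FPKM in 093 and from 63.9 ± 14.1 to 1.35 ± 2.21 FPKM in 120. Among photosystem subunits, 0 of 39 tested members rose and 21 fell in 093, and 1 rose and 22 fell in 120, with the same direction under each scaling. Among light-harvesting antenna proteins, 1 of 23 tested members rose and 15 fell in 093, and 1 rose and 15 fell in 120, also with the same direction under each scaling. Camera called both lists as shifted down, each at adjusted p = 0.31 in 093 and adjusted p = 0.43 in 120 with an estimated correlation. The antenna member that rose was a chlorophyll a/b binding family protein (Phvul.007G062000), from 0.691 ± 0.335 to 113 ± 29.0 FPKM in 093 and from 1.55 ± 0.227 to 159.6 ± 85.0 FPKM in 120.

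Sedoheptulose-bisphosphatase (Phvul.001G240200), a carbon fixation enzyme, fell from 504 ± 120.4 to 44.4 ± 1.78 FPKM in 093 and from 1131 ± 187 to 37.4 ± 11.4 FPKM in 120. Among Calvin cycle enzymes, 3 of 15 tested members rose and 5 fell in 093, and 4 rose and 6 fell in 120, while quantile normalization gave 6 rises and 4 falls in 093. Protochlorophyllide oxidoreductase A (Phvul.005G083700), which makes chlorophyll precursors, fell from 242 ± 37.1 to 11.5 ± 1.25 FPKM in 093 and from 195 ± 36.3 to 9.59 ± 3.37 FPKM in 120. Glutamyl-tRNA reductase (Phvul.008G185100) fell from 24.4 ± 7.24 to 7.31 ± 0.415 FPKM in 093 and from 70.3 ± 14.6 to 6.34 ± 1.79 FPKM in 120. In chlorophyll and tetrapyrrole synthesis, 0 of 12 tested members rose and 5 fell in 093, and 1 rose and 5 fell in 120. No description matched early light-induced proteins, so 0 loci formed that list. Of 4 plastid ribosomal proteins, 1 fell in 093, chloroplast ribosomal protein S14 (Phvul.010G068900), from 42.9 ± 24.7 to 11.3 ± 1.55 FPKM in 093, and limma called 0 in 120, where 2 had an unadjusted p under 0.05.

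Ribosomal protein L32e (Phvul.002G236400) rose from 5.61 ± 2.09 to 173 ± 4.89 FPKM in 093 and from 7.53 ± 1.56 to 146 ± 36.3 FPKM in 120, and an L7Ae/L30e family protein (Phvul.006G060900) from 1.42 ± 0.287 to 38.6 ± 1.5 FPKM in 093 and from 1.35 ± 0.730 to 33.7 ± 12.1 FPKM in 120. Among cytosolic ribosomal proteins, 53 of 65 tested members rose and 1 fell in 093, and 54 rose and 1 fell in 120, with the same direction under each scaling. Camera called them as shifted up, at adjusted p = 0.82 in 093 and adjusted p = 0.55 in 120 with an estimated correlation. In the cell division list, 17 of 50 tested members rose and 5 fell in 093, and 10 rose and 6 fell in 120. That list was led by polyribonucleotide nucleotidyltransferase (Phvul.004G011100), an RNA-processing enzyme matched by the list's words, which rose from 0.114 ± 0.0299 to 10.8 ± 0.578 FPKM in 093 and from 0.251 ± 0.0683 to 5.00 ± 1.11 FPKM in 120, and by ribonucleotide reductase 1 (Phvul.009G115100), which rose from 0.873 ± 0.494 to 11.6 ± 0.709 FPKM in 093 and from 1.36 ± 0.0459 to 11.8 ± 2.93 FPKM in 120.

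Carbohydrate enzymes changed in both directions. An alpha-amylase-like locus (Phvul.010G017600) rose from 0.937 ± 0.2002 to 51.1 ± 0.246 FPKM in 093 and from 1.62 ± 0.758 to 39.7 ± 5.56 FPKM in 120, whereas beta-amylase 6 (Phvul.005G112400) fell from 5.96 ± 1.33 to 0.384 ± 0.0423 FPKM in 093 and from 16.1 ± 3.36 to 0.279 ± 0.0721 FPKM in 120. In starch synthesis and breakdown, 9 of 36 tested members rose and 8 fell in 093, and 5 rose and 15 fell in 120, while median-ratio scaling and quantile normalization each gave 5 rises and 13 falls in 093. Sucrose synthase 4 (Phvul.009G223800) rose from 2.71 ± 0.774 to 79.3 ± 3.46 FPKM in 093 and from 2.90 ± 0.702 to 46.2 ± 13.3 FPKM in 120, and a neutral invertase (Phvul.003G118400), which splits sucrose, rose from 2.49 ± 0.483 to 50.4 ± 1.499 FPKM in 093 and from 0.685 ± 0.280 to 30.1 ± 8.88 FPKM in 120. In sucrose and trehalose metabolism, 9 of 22 tested members rose and 2 fell in 093, and 6 rose and 4 fell in 120. Galactinol synthase 2 (Phvul.001G223700), an enzyme of raffinose synthesis, rose from 0.0339 ± 0.0312 to 29.5 ± 0.467 FPKM in 093 and from 0.0101 ± 0.0176 to 4.37 ± 3.00 FPKM in 120, and seed imbibition 2 (Phvul.001G135200) rose from 0.177 ± 0.0909 to 77.8 ± 3.61 FPKM in 093 and from 0.635 ± 0.176 to 64.8 ± 3.02 FPKM in 120. In galactinol and raffinose synthesis, 5 of 10 tested members rose and 2 fell in 093, and 3 rose and 1 fell in 120.

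Among cold-regulated, dehydrin and LEA proteins, 9 of 13 tested members rose and 1 fell in 093, and 8 rose and 1 fell in 120. Cold-regulated gene 27 (COR27, Phvul.001G022200) rose from 5.17 ± 3.07 to 72.5 ± 1.79 FPKM in 093 and from 0.616 ± 0.676 to 46.3 ± 11.0 FPKM in 120. A LEA protein (Phvul.001G184600) was listed at 0 in all control libraries and stood at 21.1, 16.7 and 15.8 FPKM in the 093 cold libraries and 16.5, 14.9 and 11.8 FPKM in the 120 cold libraries. The CBF/DREB list had 3 loci and 0 passed the filter on low values. C-repeat binding factor 1 (Phvul.007G222500) had the highest value in any library, 0.450 FPKM. In the heat shock protein list, 69 of 136 tested members rose and 18 fell in 093, and 58 rose and 23 fell in 120. The mitochondrial chaperones HSP89.1 (Phvul.008G285400) and HSP60 (Phvul.007G135100) rose from 0.462 ± 0.116 to 63.1 ± 1.64 FPKM in 093 and from 1.33 ± 0.883 to 46.9 ± 2.07 FPKM in 120, and from 1.31 ± 0.216 to 80.2 ± 1.39 FPKM in 093 and from 2.29 ± 1.23 to 70.6 ± 14.2 FPKM in 120. Heat shock factor B2A (Phvul.007G067800) rose from 0.743 ± 0.388 to 8.34 ± 3.59 FPKM in 093 and from 0.696 ± 0.646 to 11.4 ± 3.94 FPKM in 120, and factor A6B (Phvul.007G061800) from 0.0381 ± 0.0214 to 4.40 ± 0.697 FPKM in 093 and from 0.0505 ± 0.0554 to 3.82 ± 1.01 FPKM in 120. Of heat shock transcription factors, 4 of 12 tested members rose and 0 fell in 093, and 9 rose and 0 fell in 120.

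Glutathione peroxidase 6 (Phvul.002G288700), which removes peroxides, rose from 83.9 ± 38.6 to 1251 ± 234 FPKM in 093 and from 90.4 ± 12.2 to 2135 ± 529.9 FPKM in 120, while catalase 2 (Phvul.009G011100) fell from 2688 ± 579.8 to 364 ± 16.0 FPKM in 093 and from 2859 ± 312 to 279 ± 21.1 FPKM in 120. Among antioxidant enzymes, 6 of 28 tested members rose and 7 fell in 093, and 5 rose and 9 fell in 120, while median-ratio scaling and quantile normalization each gave 2 rises and 9 falls in both varieties. Glutathione S-transferase tau 8 (MSTRG.9215) rose from 4.16 ± 5.21 to 173 ± 118 FPKM in 093 and from 3.79 ± 2.35 to 365 ± 280.3 FPKM in 120, and tau 9 (Phvul.009G187800) rose from 0.0197 ± 0.0215 to 9.63 ± 4.22 FPKM in 093 and from 0.0203 ± 0.0219 to 21.5 ± 7.27 FPKM in 120. Among glutathione S-transferases, 12 of 29 tested members rose and 3 fell in 093, and 9 rose and 3 fell in 120. A peroxidase (Phvul.011G128200) rose from 0.328 ± 0.370 to 14.1 ± 1.14 FPKM in 093 and from 0.128 ± 0.0971 to 57.5 ± 20.2 FPKM in 120. Another peroxidase (Phvul.004G018900) was listed at 0 in all control libraries and stood at 18.5, 16.8 and 19.4 FPKM in 093 cold and 5.56, 16.7 and 7.23 FPKM in 120 cold. Among class III peroxidases, 13 of 34 tested members rose and 5 fell in 093, and 11 rose and 9 fell in 120, while quantile normalization gave 10 rises and 12 falls in 093. The flavonoid enzymes chalcone-flavanone isomerase (Phvul.007G008600) and flavanone 3-hydroxylase (Phvul.003G261900) rose from 0.470 ± 0.241 to 120.4 ± 4.14 FPKM in 093 and from 0.320 ± 0.295 to 112 ± 13.7 FPKM in 120, and from 0.0292 ± 0.0271 to 29.4 ± 2.71 FPKM in 093 and from 0.199 ± 0.0997 to 23.2 ± 3.79 FPKM in 120. In phenylpropanoid and flavonoid synthesis, 19 of 33 tested members rose and 7 fell in 093, and 16 rose and 3 fell in 120.

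Every hormone list held called members in both varieties. Of all tested loci, 48.2% were called in 093 and 46.4% in 120. Camera called no hormone list in either cold contrast. A protein phosphatase 2C (Phvul.011G125400), a negative regulator of abscisic acid signalling, rose from 0.376 ± 0.581 to 56.6 ± 1.39 FPKM in 093 and from 0.551 ± 0.2001 to 74.5 ± 34.1 FPKM in 120. In the abscisic acid list, 25 of 71 tested members rose and 9 fell in 093, and 25 rose and 12 fell in 120, while in 093 median-ratio scaling gave 15 rises and 11 falls and quantile normalization 17 and 12. The jasmonate repressor JAZ1 (Phvul.009G225300) rose from 20.5 ± 22.2 to 261 ± 7.28 FPKM in 093 and from 9.96 ± 1.46 to 369.9 ± 63.7 FPKM in 120, and lipoxygenase 2 (Phvul.006G016900) rose from 2.73 ± 0.143 to 64.3 ± 3.86 FPKM in 093 and from 4.16 ± 1.61 to 164 ± 81.0 FPKM in 120. In the jasmonate list, 20 of 44 tested members rose and 3 fell in 093, and 17 rose and 9 fell in 120. In the ethylene list, a locus described as ACC synthase 10 (Phvul.002G152200), whose Arabidopsis namesake is an aminotransferase without ACC synthase activity, fell from 20.3 ± 3.37 to 1.34 ± 0.777 FPKM in 093 and from 26.4 ± 3.91 to 0.631 ± 0.198 FPKM in 120, and EBF1 (Phvul.001G051300), which targets ethylene signalling proteins for degradation, rose from 0.922 ± 1.48 to 17.6 ± 1.65 FPKM in 093 and from 0.581 ± 0.863 to 6.64 ± 1.33 FPKM in 120. Of that list, 7 of 8 tested members rose and 1 fell in 093, and 3 rose and 1 fell in 120.

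An auxin-responsive gene (Phvul.006G142300) rose from 0.654 ± 0.320 to 46.7 ± 1.3 FPKM in 093 and from 0.376 ± 0.0214 to 123 ± 26.9 FPKM in 120, and auxin-induced protein 13 (Phvul.001G164900) rose from 0.150 ± 0.133 to 16.3 ± 0.814 FPKM in 093 and from 0.193 ± 0.132 to 3.11 ± 1.31 FPKM in 120. Among auxin-responsive genes, 9 of 26 tested members rose and 3 fell in 093, and 5 rose and 9 fell in 120. Gibberellin 2-oxidases inactivate gibberellins, and those at Phvul.006G165000 and Phvul.002G049000 rose from 0.332 ± 0.492 to 12.3 ± 0.178 FPKM in 093 and from 0.390 ± 0.184 to 10.0 ± 5.31 FPKM in 120, and from 5.08 ± 1.62 to 61.2 ± 3.41 FPKM in 093 and from 1.71 ± 1.12 to 8.88 ± 3.79 FPKM in 120. In the gibberellin list, 5 of 9 tested members rose and 1 fell in 093, and 4 rose and 1 fell in 120. Cytokinin oxidases 6 (Phvul.005G034000) and 7 (Phvul.001G038800), which break down cytokinins, fell from 5.96 ± 1.79 to 0.0773 ± 0.0788 FPKM in 093 and from 3.35 ± 0.679 to 0.0103 ± 0.0179 FPKM in 120, and from 8.28 ± 0.730 to 1.21 ± 0.253 FPKM in 093 and from 5.97 ± 0.647 to 1.37 ± 0.692 FPKM in 120. In the cytokinin list, 2 of 22 tested members rose and 5 fell in 093, and 3 rose and 5 fell in 120.

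The transcription factor NAC73 (Phvul.006G181500) rose from 0.0722 ± 0.0474 to 65.9 ± 1.74 FPKM in 093 and from 0.214 ± 0.0966 to 75.3 ± 45.5 FPKM in 120, and a NAC locus with 2 gene names (MSTRG.10900) rose from 0.0974 ± 0.0996 to 83.9 ± 15.2 FPKM in 093 and from 0.155 ± 0.117 to 34.8 ± 6.12 FPKM in 120. Among NAC factors, 36 of 54 tested members rose and 1 fell in 093, and 32 rose and 4 fell in 120, with the same direction under each scaling. WRKY40 (Phvul.010G161100), of a family that controls defence genes, rose from 0.811 ± 0.355 to 35.2 ± 1.36 FPKM in 093 and from 0.453 ± 0.250 to 31.5 ± 5.92 FPKM in 120. A second WRKY40 (Phvul.001G042200) was listed at 0 in 093 control, stood at 48.6, 46.2 and 48.2 FPKM in 093 cold and rose from 0.0904 ± 0.0351 to 49.7 ± 27.6 FPKM in 120. Among WRKY factors, 31 of 52 tested members rose and 4 fell in 093, and 37 rose and 4 fell in 120, with the same direction under each scaling. Ethylene response factor 5 (MSTRG.4148) rose from 0.282 ± 0.489 to 30.5 ± 4.99 FPKM in 093 and from 1.99 ± 2.18 to 28.8 ± 4.01 FPKM in 120, and an integrase-type factor (Phvul.008G092800) rose from 0.0579 ± 0.0449 to 14.3 ± 2.56 FPKM in 093 and from 0.287 ± 0.252 to 13.3 ± 1.60 FPKM in 120. Among AP2/ERF factors, 12 of 29 tested members rose and 3 fell in 093, and 11 rose and 6 fell in 120. MYB116 (Phvul.002G317000) rose from 0.253 ± 0.190 to 17.9 ± 0.798 FPKM in 093 and from 0.0524 ± 0.00561 to 27.8 ± 0.408 FPKM in 120, and a MYB-like factor (Phvul.002G304400) fell from 8.40 ± 0.635 to 0.322 ± 0.0449 FPKM in 093 and from 17.1 ± 3.36 to 0.375 ± 0.194 FPKM in 120. Among MYB factors, 21 of 54 tested members rose and 6 fell in 093, and 14 rose and 7 fell in 120, while median-ratio scaling and quantile normalization each gave 12 rises and 11 falls in 093.

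The calmodulin-like CML11 loci Phvul.007G111200 and Phvul.007G278900 rose from 1.10 ± 1.24 to 50.3 ± 4.49 FPKM in 093 and from 0.253 ± 0.0966 to 56.8 ± 8.50 FPKM in 120, and from 0.225 ± 0.308 to 20.4 ± 1.27 FPKM in 093 and from 0.537 ± 0.367 to 83.6 ± 33.2 FPKM in 120. Among calcium sensors and kinases, 29 of 78 tested members rose and 5 fell in 093, and 25 rose and 7 fell in 120. The clock genes pseudo-response regulator 5 (PRR5, Phvul.009G045000) and GIGANTEA (GI, Phvul.007G083500), which keep daily time, rose from 19.6 ± 5.24 to 107 ± 5.03 FPKM in 093 and from 0.211 ± 0.205 to 104 ± 29.3 FPKM in 120, and from 22.5 ± 2.37 to 121 ± 6.34 FPKM in 093 and from 0.501 ± 0.302 to 122 ± 27.7 FPKM in 120. In the circadian clock list, 5 of 7 tested members rose and 1 fell in 093, and 6 rose and 0 fell in 120, with the same direction under each scaling. The member that fell in 093 was a PRR7/PRR3 locus (MSTRG.12776), chosen after its values were seen, from 31.4 ± 8.33 to 13.9 ± 0.838 FPKM in 093.

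Expansin A8 (Phvul.009G142800), which loosens cell walls, fell from 91.9 ± 41.6 to 3.87 ± 0.496 FPKM in 093 and from 91.3 ± 50.0 to 0.661 ± 0.148 FPKM in 120. In cell wall loosening, 9 of 34 tested members rose and 12 fell in 093, and 11 rose and 15 fell in 120. The aquaporin PIP2 (Phvul.004G082700) rose from 12.9 ± 3.29 to 321 ± 13.1 FPKM in 093 and from 31.9 ± 7.67 to 166 ± 84.6 FPKM in 120. Among aquaporins, 5 of 23 tested members rose and 4 fell in 093, and 4 rose and 9 fell in 120, while in 093 median-ratio scaling gave 5 rises and 8 falls and quantile normalization 5 and 10. The desaturase FAD8 (Phvul.006G068600), which adds double bonds to plastid lipids, fell from 4.43 ± 1.53 to 1.29 ± 0.0542 FPKM in 093 and from 16.1 ± 8.33 to 2.01 ± 0.580 FPKM in 120. Without 093 control library 3 its log2 change in 093 went from -1.21 to -0.99 and the call ended. FAD5 (Phvul.010G156200) fell from 16.1 ± 1.901 to 1.82 ± 0.949 FPKM in 120. Among fatty acid desaturases, 2 of 8 tested members rose and 1 fell in 093, and 0 rose and 3 fell in 120. Lipid transfer proteins at Phvul.007G058500 and Phvul.003G217100 rose from 0.174 ± 0.0697 to 20.9 ± 9.25 FPKM in 093 and from 0.0763 ± 0.0395 to 63.5 ± 32.2 FPKM in 120, and from 3.94 ± 5.83 to 18.0 ± 0.204 FPKM in 093 and from 2.69 ± 1.42 to 84.3 ± 11.5 FPKM in 120. In the lipid transfer list, 7 of 16 tested members rose and 3 fell in 093, and 9 rose and 2 fell in 120.

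The defence protein osmotin 34 (Phvul.002G155500) was listed at 0 in all control libraries and stood at 22.7, 23.2 and 21.5 FPKM in 093 cold and 16.8, 20.9 and 18.0 FPKM in 120 cold. Chitinase-like protein 2 (MSTRG.11420) fell from 71.9 ± 5.84 to 2.92 ± 2.00 FPKM in 093 and from 34.2 ± 11.8 to 1.19 ± 1.04 FPKM in 120. Among pathogenesis-related proteins and chitinases, 6 of 22 tested members rose and 4 fell in 093, and 11 rose and 6 fell in 120. The NBS-LRR disease resistance genes Phvul.003G247400 and MSTRG.4272 rose from 0.164 ± 0.0528 to 26.5 ± 1.60 FPKM in 093 and from 0.113 ± 0.110 to 21.0 ± 9.67 FPKM in 120, and from 1.65 ± 1.15 to 19.2 ± 2.71 FPKM in 093 and from 1.07 ± 0.302 to 35.2 ± 4.49 FPKM in 120. Among NBS-LRR genes, 35 of 126 tested members rose and 13 fell in 093, and 34 rose and 20 fell in 120. Median-ratio scaling gave 25 rises and 19 falls in 093 and 30 and 24 in 120. Quantile normalization gave 24 and 19 in 093 and 28 and 27 in 120.

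Of the lists for tissues other than leaf, seed storage and cotyledon proteins held 10 tested loci, all of them lipid transfer family members that the lipid transfer list holds too. There, 5 of 10 tested members rose and 1 fell in 093, and 7 rose and 0 fell in 120. In the nodule and root list, root hair specific 2 (Phvul.002G150200) fell from 4.33 ± 1.80 to 0.240 ± 0.113 FPKM in 093 and from 7.69 ± 0.753 to 0.0642 ± 0.0523 FPKM in 120 and root hair specific 16 (Phvul.004G173300) rose from 2.15 ± 0.714 to 16.6 ± 1.54 FPKM in 093 and from 1.78 ± 0.131 to 13.04 ± 1.62 FPKM in 120. In that list, 4 of 10 tested members rose and 2 fell in 093, and 3 rose and 3 fell in 120. No pollen germination related 2 (Phvul.007G190600) rose from 5.16 ± 0.928 to 13.2 ± 1.07 FPKM in 093 and from 3.65 ± 0.984 to 10.9 ± 1.07 FPKM in 120, with a log2 change in 093 of 1.21 that median-ratio scaling lowered to 0.74 and quantile normalization to 0.80. A pollen Ole e 1 protein (Phvul.001G089800) was listed at 0 in 093 cold and stood at 0.543, 3.42 and 1.23 FPKM in 093 control. The fitted fall went to -0.89 without 093 control library 2, under the minimum change, and its call ended. In the flower and pollen list, 3 of 13 tested members rose and 2 fell in 093, and 2 rose and 0 fell in 120, while in 093 median-ratio scaling gave 1 rise and 2 falls and quantile normalization 0 and 4.

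**Figure D2:**
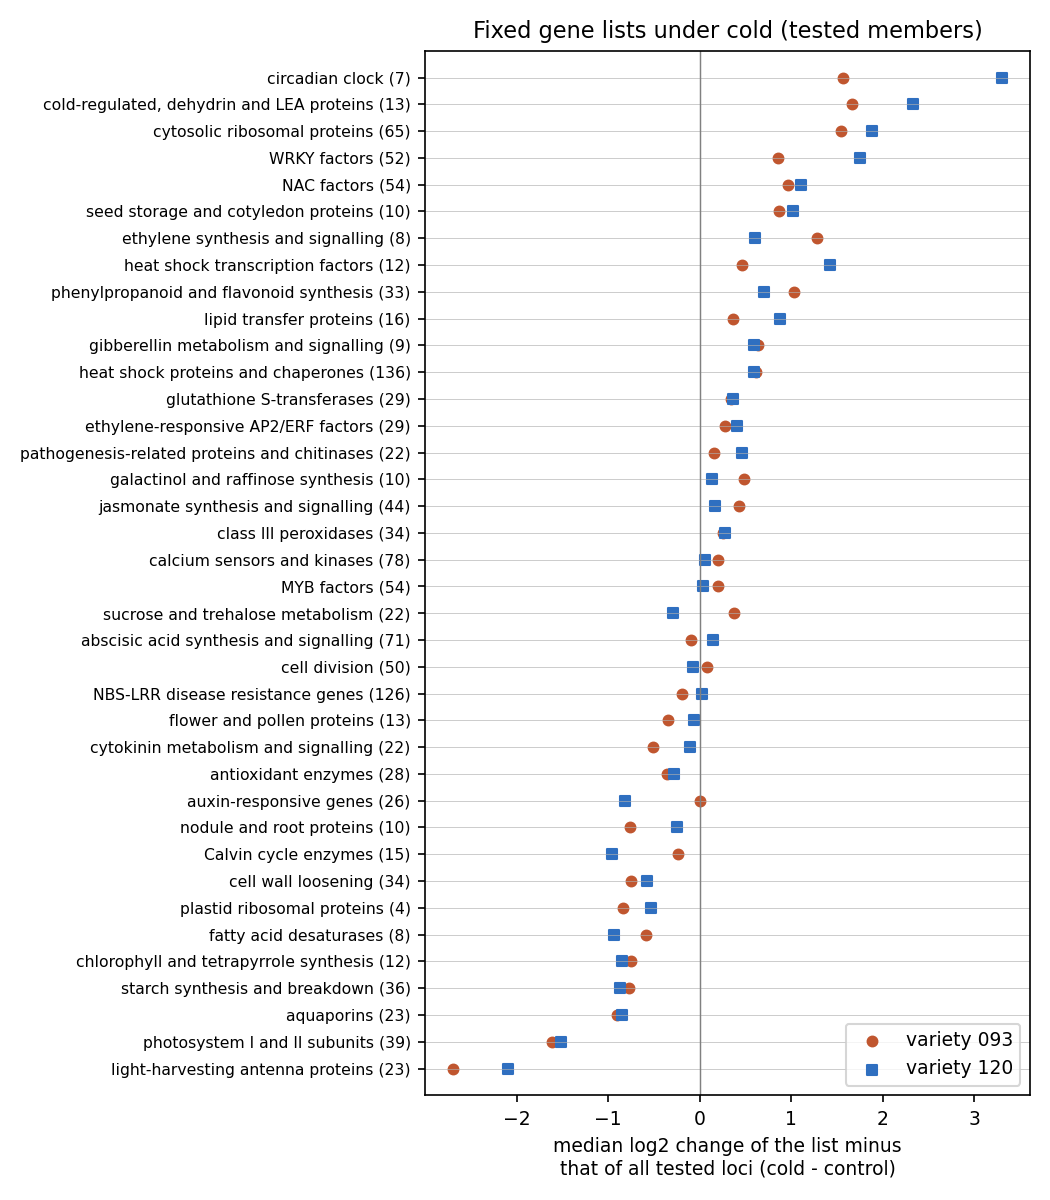
Median log2 change under cold of each gene list minus the median of all tested loci (x axis) in varieties 093 and 120, for the 38 lists with tested members (y axis). Light-harvesting antenna proteins lay at -2.70 in 093 and -2.09 in 120 and cytosolic ribosomal proteins at 1.55 and 1.89, on the same side of 0 under each scaling, while Calvin cycle enzymes changed side in both varieties with quantile normalization.

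Against all other loci in 093, camera with its preset correlation called 5 of 37 lists. Cytosolic ribosomal proteins (adjusted p = 3.5e-08), NAC factors (adjusted p = 6.3e-04) and WRKY factors (adjusted p = 0.033) were shifted up, each at adjusted p = 0.82 with an estimated correlation. Relative to all loci their medians were 1.55, 0.97 and 0.85 log2. Photosystem subunits (adjusted p = 7.5e-09) and antenna proteins (adjusted p = 8.3e-06) were shifted down, each at adjusted p = 0.31 with an estimated correlation, with relative medians of -1.62 and -2.70. The 32 other lists were not called, with a lowest adjusted p of 0.13 for chlorophyll and tetrapyrrole synthesis.

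In 120, camera called 8 of 37 lists. Cytosolic ribosomal proteins (adjusted p = 5.4e-10), WRKY factors (adjusted p = 1.1e-04), NAC factors (adjusted p = 0.0011), the circadian clock (adjusted p = 0.0039) and heat shock transcription factors (adjusted p = 0.048) were shifted up, each at adjusted p = 0.55 with an estimated correlation. Starch synthesis and breakdown was shifted down (adjusted p = 0.010), at adjusted p = 0.55 with an estimated correlation. Photosystem subunits (adjusted p = 1.2e-06) and antenna proteins (adjusted p = 7.4e-04) were shifted down, each at adjusted p = 0.43 with an estimated correlation. Relative medians ran from -2.09 for antenna proteins to 3.31 for the clock. The heat shock factor call ended without 093 control library 2 (adjusted p = 0.061), 093 control library 3 (0.061), 120 control library 2 (0.053) or 120 cold library 2 (0.056). It also ended with a pseudocount of 0.1 (adjusted p = 0.052), no filter (0.15), TPM (0.051), library weights (0.060), only the groups compared (0.056) or the replicate block (0.0505), in a range over alternatives of 0.022 to 0.55. The 29 other lists were not called, with a lowest adjusted p of 0.051 for cold-regulated, dehydrin and LEA proteins, which had a relative median of 2.33.

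With the estimated correlation, camera called 0 lists in any contrast, and 2, 3, 1, 1 and 1 of 37 lists had an unadjusted p under 0.05 in the cold response of 093, that of 120, the difference, and the varieties without and under cold. Counts adjusted over the list alone equalled those above in the cold contrasts except in 4 lists of 120 and 1 of 093. In 120, adjusted over the list alone, galactinol and raffinose synthesis had 3 rises and 0 falls, photosystem subunits 1 and 23, the circadian clock 7 and 0, and calcium sensors and kinases 25 and 6. In 093, adjusted over the list alone, antioxidant enzymes had 6 and 6. The median and the mean, or the median relative to all loci and the camera direction, differed in sign in 093 for Calvin cycle enzymes, antioxidant enzymes, the abscisic acid list, desaturases, aquaporins, pathogenesis-related proteins, NBS-LRR genes and the nodule and root list. In 120 they differed for sucrose and trehalose metabolism and the cytokinin list. None of these lists was called there. With median-ratio scaling and with quantile normalization alike, rises were fewer than with the deposited scaling in 27 of 38 lists in 093 and in 16 in 120.

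Among annotated terms, the cytosolic large ribosomal subunit had 99 of 116 members higher in 093 (adjusted p = 1.5e-28, Fisher exact test) and 94 of 116 in 120 (adjusted p = 7.0e-30, exact). The small-subunit processome had 34 and 32 of 37 members higher, and the proteasome 44 and 42 of 71. Response to chitin had 24 of 41 members higher in 093 (adjusted p = 0.015, exact) and 35 in 120 (adjusted p = 3.6e-12, exact). Response to cold had 71 of 156 higher in 093 (adjusted p = 0.016, exact) and 74 in 120 (adjusted p = 8.5e-06, exact). The chloroplast thylakoid membrane had 87 of 227 members lower in 093 (adjusted p = 1.0e-14, exact) and 108 in 120 (adjusted p = 1.1e-20, exact). Of 10 members of the plastid NAD(P)H dehydrogenase complex, 7 fell in 093 (adjusted p = 0.0078, exact) and 10 in 120 (adjusted p = 6.9e-06, exact). In all, 69 terms were enriched among higher and 33 among lower loci in 093, and 62 and 71 in 120, of 1006 tested.

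The responses differed most for genes whose level changed in 1 variety or started from different levels. WRKY33 (Phvul.010G062500), a regulator of defence genes, went from 0.440 ± 0.555 to 0.629 ± 0.273 FPKM in 093, which was not called (adjusted p = 0.43), and rose from 0.0838 ± 0.0393 to 41.1 ± 10.8 FPKM in 120. The difference in log2 response was 5.02 (SE 0.362, adjusted p = 5.9e-06). The sugar transporter family gene MtN3 (Phvul.002G283800) rose from 0.178 ± 0.113 to 35.6 ± 3.01 FPKM in 093 and was not called in 120, where it went from 0.811 ± 0.290 to 0.964 ± 0.659 FPKM (difference -4.88, adjusted p = 2.8e-06). PRR5 (Phvul.009G045000) and GI (Phvul.007G083500) had higher responses in 120 by 4.00 and 3.96 log2 (adjusted p = 1.2e-05 and 3.5e-06), starting from lower controls in 120.

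Opposite responses were called for a GroES-like dehydrogenase (Phvul.011G018000), which went from 14.8 ± 5.09 to 1.53 ± 0.370 FPKM in 093 and from 0.859 ± 0.152 to 11.9 ± 4.03 FPKM in 120 (difference 5.35, adjusted p = 3.5e-06). An alpha-crystallin domain protein (Phvul.008G264700) went from 148 ± 40.1 to 65.2 ± 3.26 FPKM in 093 and from 6.48 ± 1.83 to 73.1 ± 16.2 FPKM in 120 (difference 4.45), and its fall in 093 of -1.13 log2 became -0.97 without 093 control library 2, which ended that call. A pyridoxal phosphate phosphatase-related locus (Phvul.010G141200) and a bicarbonate transporter (Phvul.005G174400) rose in 093 and fell in 120, going from 0.415 ± 0.132 to 8.41 ± 0.186 FPKM in 093 and from 28.7 ± 3.45 to 4.29 ± 1.41 FPKM in 120, and from 0.446 ± 0.116 to 12.1 ± 0.538 FPKM in 093 and from 54.9 ± 9.10 to 15.0 ± 0.858 FPKM in 120. Their differences were -5.26 and -4.98. A divalent ion symporter (Phvul.004G111900) rose from 0.666 ± 0.215 to 51.7 ± 12.7 FPKM in 120, with a difference of 4.84.

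An MLP-like protein (Phvul.009G252400) rose from 0.0406 ± 0.0199 to 81.3 ± 6.39 FPKM in 093 and from 147 ± 102 to 296 ± 118 FPKM in 120, with a difference of -5.16. Its log2 change in 120 of 1.14 (adjusted p = 0.021) became 0.74 without 120 control library 1 and 0.85 without 120 cold library 1, and without 120 control library 3 it was 1.02 with adjusted p = 0.069. Each of these omissions ended the call, in a range of adjusted p over alternatives of 5.4e-05 to 0.099. PsbQ-like 2 (Phvul.003G045300) stood at 118, 0.825 and 103 FPKM in 093 control and 0.164, 8.13 and 11.0 FPKM in 093 cold, and went from 0.372 ± 0.219 to 9.55 ± 3.17 FPKM in 120, where its change was not called. Its difference of 5.40 (SE 1.91, adjusted p = 0.049) lost its call on omission of any 1 library other than 093 control library 2, with adjusted p between 0.053 and 0.11, and also with no filter (0.084), no variance trend (0.0502), the replicate block (0.053) and without 093 control library 3 and 120 cold library 3 together (0.14), in a range over alternatives of 0.00095 to 0.14. Without 093 control library 2 the adjusted p was 0.00095. A MIND complex protein (Phvul.004G106800) was listed at 0 in 120 cold. It stood at 6.29, 8.68 and 0 FPKM in 120 control, 10.3, 0 and 0 FPKM in 093 control and 17.1, 19.02 and 17.9 FPKM in 093 cold.

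**Figure D3:**
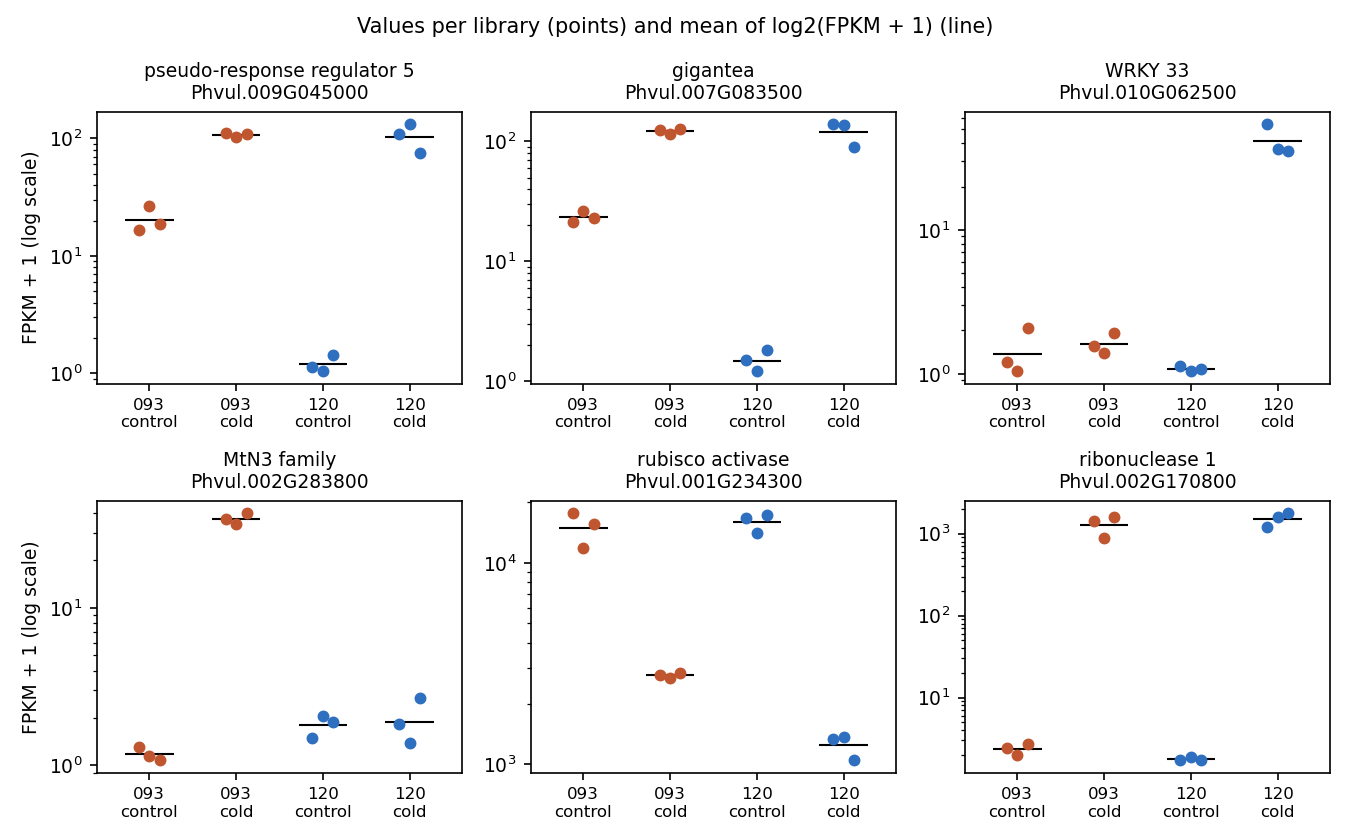
FPKM + 1 on a log axis (y axis) in each of the 12 libraries (points) by group (x axis) for PRR5, GI, WRKY33, MtN3, rubisco activase and ribonuclease 1, with lines at the mean of the log2 values. WRKY33 reached 41.1 ± 10.8 FPKM in 120 cold against 0.629 ± 0.273 in 093 cold, and MtN3 0.964 ± 0.659 against 35.6 ± 3.01.

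For the difference of the responses, limma called 2886 of 14716 loci (19.6%), 956 higher and 1930 lower in 120. The median log2 difference of all loci was -0.23. Median-ratio scaling moved it by 0.23 and gave 1352 higher and 1228 lower calls, and quantile normalization moved it by 0.19 and gave 1276 of each. Of loci called in the same direction in both varieties, 758 differed in size.

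Camera called 4 of 37 lists for the difference, each at adjusted p = 0.77 with an estimated correlation. The circadian clock (adjusted p = 2.0e-05) had 5 of 7 members higher in 120 and 0 lower, with a relative median of 3.34. WRKY factors (adjusted p = 0.0035) had 10 of 52 higher and 3 lower. Their call ended with no filter (adjusted p = 0.10) or a filter at 5 FPKM (0.089), in a range over alternatives of 0.0013 to 0.77. Heat shock transcription factors (adjusted p = 0.033) had 5 of 12 higher and 0 lower. Their call ended without 093 control library 1 (adjusted p = 0.078), 093 control library 2 (0.081), 120 control library 2 (0.070) or 120 cold library 2 (0.085). It also ended with a pseudocount of 0.1 (adjusted p = 0.075), no filter (0.10), TPM (0.10), median-ratio (0.12) or quantile scaling (0.12), in a range over alternatives of 0.0032 to 0.77. Auxin-responsive genes (adjusted p = 0.028) had 2 of 26 higher and 11 lower. Their call ended without 093 control library 3 (adjusted p = 0.055), 120 control library 1 (0.052) or both 093 control library 3 and 120 cold library 3 (0.13). It also ended with no filter (adjusted p = 0.55), a filter at 5 FPKM (0.19) or library weights (0.070), in a range of 0.0064 to 0.77. The direction of these 4 lists was the same under each scaling.

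The other 33 lists were not called, with a lowest adjusted p of 0.14 for sucrose and trehalose metabolism. Of their members, the difference was lower in 120 for 8 of 22 sucrose and trehalose genes, 10 of 36 starch genes, 7 of 15 Calvin cycle enzymes, 11 of 23 aquaporins and 4 of 8 desaturases, and higher for 0, 1, 1, 2 and 0, with more lower than higher under each scaling. FAD5 (Phvul.010G156200) had a difference of -2.23, galactinol synthase 2 (Phvul.001G223700) -2.68, the aquaporin PIP2 (Phvul.004G082700) -2.30 and asparagine synthase 1 (MSTRG.9850) -2.89. Counts adjusted over the list alone were 1 higher and 11 lower for starch, 0 and 0 for antioxidant enzymes, 4 and 5 for phenylpropanoids, 5 and 13 for jasmonate, 4 and 2 for cytokinin, and 0 and 0 for cytosolic ribosomal proteins, where over all loci they were 1 and 10, 0 and 1, 4 and 4, 5 and 12, 3 and 2, and 0 and 1. Quantile normalization turned the jasmonate count to 5 and 4 and that of cytosolic ribosomal proteins to 1 and 0, and median-ratio scaling the latter to 3 and 0. In the same sense sign differed for antenna proteins, antioxidant enzymes, calcium sensors, MYB factors, cell wall loosening and flower and pollen proteins.

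Among terms, starch and sucrose metabolism had 85 of 315 members with a lower response in 120 (adjusted p = 2.6e-08, Fisher exact test). Plant hormone signal transduction had 99 of 446 lower (adjusted p = 2.9e-05, exact) and oligopeptide transport 20 of 44 (adjusted p = 5.2e-05, exact). Response to chitin had 12 of 41 members with a higher response (adjusted p = 0.0036, exact). In all, 3 terms were enriched among higher and 50 among lower loci.

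Without cold, 5 of 7 clock genes were lower in 120 than in 093. PRR5 (Phvul.009G045000) stood at 19.6 ± 5.24 FPKM in 093 control and 0.211 ± 0.205 in 120 control, and GI (Phvul.007G083500) at 22.5 ± 2.37 and 0.501 ± 0.302. A lipoxygenase 1 locus with 2 gene names (MSTRG.12139), of a family that oxidises fatty acids, stood at 0.232 ± 0.0464 in 093 and 124 ± 23.1 in 120, whereas lipoxygenase 3 (Phvul.002G228700) stood at 123 ± 58.1 and 0.215 ± 0.0757. A copper transport protein (Phvul.008G282200) was higher in 120 at 57.8 ± 9.23 against 0.322 ± 0.177. An acyl transferase (Phvul.010G047900) was lower in 120 at 0.0166 ± 0.0205 against 41.8 ± 9.24, as was a HAD hydrolase (Phvul.007G056000) at 2.38 ± 1.73 against 133 ± 70.8. A ferredoxin-like locus (MSTRG.7297) was listed at 0 in all 6 libraries of 120 and stood at 186, 145 and 158 FPKM in 093 control. Galacturonosyltransferase-like 3 (Phvul.003G027400) was listed at 0 in the same 6 libraries and stood at 24.6, 22.9 and 30.6 FPKM in 093 control.

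Between the controls, limma called 1586 loci (10.8%), 933 higher and 653 lower in 120. PRR5 differed by -4.07 log2 (SE 0.224, adjusted p = 2.3e-07) and was lower in 3 of 3 libraries. The groups did not overlap for 39.7% of all tested loci, where chance gives 10%. Median-ratio scaling gave 797 higher and 795 lower calls and quantile normalization 763 and 766. Camera called the circadian clock alone, of 37 lists (adjusted p = 3.4e-07; adjusted p = 0.64 with an estimated correlation), with 5 of 7 members lower under each scaling and a relative median of -3.06. The 36 other lists were not called, with a lowest adjusted p of 0.20 for antenna proteins. Counts adjusted over the list alone gave 3 higher and 3 lower for sucrose and trehalose metabolism, 0 and 0 for heat shock factors, 0 and 1 for plastid ribosomal proteins and 14 and 11 for NBS-LRR genes, where over all loci they were 2 and 3, 0 and 1, 0 and 0, and 13 and 11. In the same sense sign differed for galactinol and raffinose synthesis, MYB factors, cytosolic ribosomal proteins and NBS-LRR genes. The plastid NAD(P)H dehydrogenase complex had 6 of 10 members higher in 120 (adjusted p = 0.0054, Fisher exact test), chlorophyll biosynthesis 9 of 30 (adjusted p = 0.0097, exact), and circadian rhythm 11 of 52 lower (adjusted p = 0.014, exact), among 8 terms higher and 1 lower.

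Under cold, WRKY33 (Phvul.010G062500) was higher in 120 than in 093, at 41.1 ± 10.8 against 0.629 ± 0.273 FPKM (log2 difference 4.67), and MtN3 (Phvul.002G283800) was lower, at 0.964 ± 0.659 against 35.6 ± 3.01 (-4.27). PRR5 stood at 104 ± 29.3 and 107 ± 5.03 and was not called (-0.07, adjusted p = 0.84). Galactinol synthase 2 was lower in 120, at 4.37 ± 3.00 against 29.5 ± 0.467. So was the water channel PIP2;4, at 4.85 ± 0.892 against 23.2 ± 1.51. Lipoxygenase 3 stayed lower in 120 (-5.31), and the acyl transferase too (-4.78).

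Between the varieties under cold, limma called 1861 loci (12.6%), 827 higher and 1034 lower in 120. The groups did not overlap for 53.4% of all tested loci, where chance gives 10%. The median of all loci was -0.12. Median-ratio scaling moved it by 0.13 and gave 981 higher and 734 lower calls, and quantile normalization moved it by 0.10 and gave 957 and 798. Camera called sucrose and trehalose metabolism alone, of 37 lists (adjusted p = 0.0054; adjusted p = 0.98 with an estimated correlation), with 1 of 22 members higher and 5 lower, a direction shared by each scaling. That call ended without 120 cold library 3 (adjusted p = 0.059), without that and 093 control library 3 (0.055) and with library weights (0.054), in a range over alternatives of 0.0012 to 0.98. The 36 other lists were not called, with a lowest adjusted p of 0.070 for WRKY factors, of which 11 of 52 were higher and 2 lower. Counts adjusted over the list alone gave 6 higher and 2 lower for abscisic acid, 3 and 1 for lipid transfer proteins and 15 and 19 for NBS-LRR genes, where over all loci they were 5 and 2, 2 and 1, and 15 and 18. The NBS-LRR count became 16 and 14 under median-ratio scaling and under quantile normalization. In the same sense sign differed for 14 lists, none of them called. Response to chitin had 13 of 41 members higher in 120 (adjusted p = 0.00021, Fisher exact test), nitrate assimilation 12 of 34 lower (adjusted p = 0.00083, exact) and water channel activity 9 of 29 lower (adjusted p = 0.011, exact), among 3 terms higher and 18 lower. Called in both comparisons of the varieties were 190 loci higher and 191 lower in 120, where 52.4 and 45.9 would be shared by independent sets, and 55 in opposite directions. Across loci the differences without and under cold correlated with r = 0.27 and rho = 0.14.

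**Figure D4:**
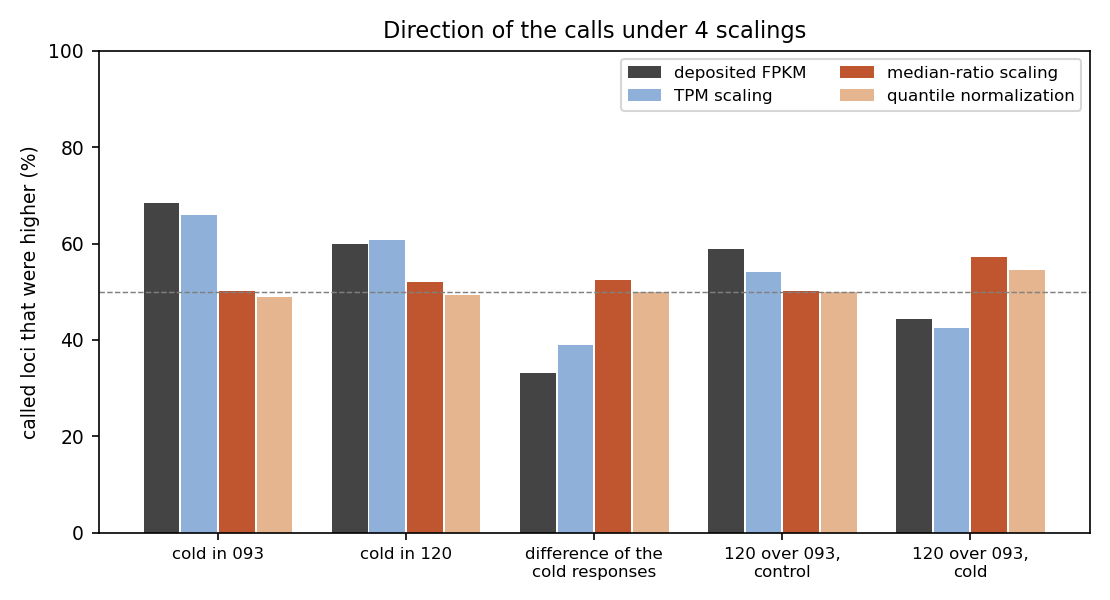
Percent of called loci that were higher (y axis) in each of the 5 contrasts (x axis) under the 4 scalings of FPKM: as deposited, equal totals (TPM), median-ratio and quantile. For the cold response in 093 it was 68.4, 66.0, 50.1 and 49.0%, and for the difference of the responses it moved from 33.1% as deposited to 52.4% with median-ratio scaling.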

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

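Of the tests in this part, the redrawing of treatment labels was chosen only after the result was seen, and the requirement that the median of the cycling DOF factors lie below its bound by more than the members' spread was added after that median was seen.

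The difference of the cold responses was called for 2886 loci. When variety labels were redrawn within treatments, 2 of 100 splits gave as many calls, the real one included, and the highest other was 3326. That split exchanged the varieties within 1 treatment as a whole, and without it the highest was 1257. Redrawing variety labels also mixes the varieties within groups, which differed at 1586 loci without cold and 1861 under cold, and so widens the spread. It therefore tests any difference of the varieties and does not exclude chance for the difference of the responses. When treatment labels were redrawn within varieties, 10 of 100 splits gave as many, which does not exclude chance for this way of drawing, with a highest other of 10339. All 9 redrawn splits that did so kept most labels in 1 variety and swapped most in the other, and the remaining ones reached at most 896. Splits of that kind add the cold response itself to the difference, so the structure of the samples that they point to is the division into treatments.

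Clock genes were lower in 120 than in 093 without cold. The 7 members of the clock list had a median log2 difference of -2.97 (SD 1.64) between the controls and -0.07 under cold. Control leaves of the varieties taken at different times of day may explain this. Cycling DOF factors, which peak at another time of day than GIGANTEA, were then to be higher in 120 control by at least 1. Their median was 0.39 (SD 0.79, 5 genes, from -0.09 to 1.78), under the bound of 0.5 set against that explanation but by less than their spread, so the sampling time and a difference of the clock between the varieties cannot be told apart. A variety difference stays open and untested. Sampling time also limits calls between controls and for the difference of the responses.

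The remaining values are called differences of the log2 cold responses (120 minus 093). With a group under 1 FPKM, they depend on the pseudocount and are no folds. They were higher in 120 for PRR5 Phvul.009G045000 (4.00), GI Phvul.007G083500 (3.96), WRKY33 Phvul.010G062500 (5.02), PsbQ-like 2 Phvul.003G045300 (5.40, adjusted p = 0.049), the GroES-like dehydrogenase Phvul.011G018000 (5.35), the divalent ion symporter Phvul.004G111900 (4.84), the alpha-crystallin domain protein Phvul.008G264700 (4.45) and the HAD hydrolase Phvul.007G056000 (4.35). The PsbQ-like call was lost on omission of any 1 library other than 093 control library 2, with adjusted p between 0.053 and 0.11, and with no filter (0.084), no variance trend (0.0502) and the replicate block (0.053), in a range over alternatives of 0.00095 to 0.14. Smaller positive differences were those of the peroxidase Phvul.011G128200 (2.09), chloroplast ribosomal protein S14 Phvul.010G068900 (1.76), the auxin-responsive gene Phvul.006G142300 (1.60), the lipid transfer protein Phvul.007G058500 (1.60), CML11 Phvul.007G278900 (1.56), the PAR1 protein Phvul.010G006000 (1.36), lipoxygenase 3 Phvul.002G228700 (1.28) and the NBS-LRR gene MSTRG.4272 (1.13). The fitted 4.09 of galacturonosyltransferase-like 3 Phvul.003G027400, listed at 0 in all 6 libraries of 120, and the fitted -5.13 of the MIND complex protein Phvul.004G106800, listed at 0 in 120 cold, rest on the pseudocount and are no folds.

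Differences lower in 120 by more than 2 were those of the pyridoxal phosphate phosphatase-related locus Phvul.010G141200 (-5.26), the MLP-like protein Phvul.009G252400 (-5.16), the bicarbonate transporter Phvul.005G174400 (-4.98), MtN3 Phvul.002G283800 (-4.88), lipoxygenase 1 MSTRG.12139 (-4.38), the pectin methylesterase inhibitor Phvul.002G318500 (-3.84), the copper transport protein Phvul.008G282200 (-3.43), asparagine synthase 1 MSTRG.9850 (-2.89), galactinol synthase 2 Phvul.001G223700 (-2.68), the aquaporin PIP2 Phvul.004G082700 (-2.30), FAD5 Phvul.010G156200 (-2.23) and auxin-induced protein 13 Phvul.001G164900 (-2.18). Smaller ones were those of the glycosyl hydrolase Phvul.001G219800 (-1.83), gibberellin 2-oxidase Phvul.002G049000 (-1.51), expansin A8 Phvul.009G142800 (-1.50), the Ntn hydrolase Phvul.001G025000 (-1.47), PIP2;4 Phvul.011G079300 (-1.41), the NAC locus MSTRG.10900 (-1.32), FAD8 Phvul.006G068600 (-1.21), polyribonucleotide nucleotidyltransferase Phvul.004G011100 (-1.16) and the AMP-dependent synthetase Phvul.006G079500 (-1.05). Others were those of glutamyl-tRNA reductase Phvul.008G185100 (-1.71), sedoheptulose-bisphosphatase Phvul.001G240200 (-1.46), beta-amylase 6 Phvul.005G112400 (-1.41), rubisco activase Phvul.001G234300 (-1.26), photosystem II subunit O-2 Phvul.002G024000 (-1.04) and the chaperone HSP89.1 Phvul.008G285400 (-1.03). As lists, the median difference was 3.11 for the circadian clock, 0.76 for heat shock transcription factors, 0.46 for WRKY factors and -0.96 for auxin-responsive genes, each at adjusted p = 0.77 with an estimated correlation. The WRKY call ended with no filter (adjusted p = 0.10) or a filter at 5 FPKM (0.089), in a range over alternatives of 0.0013 to 0.77. The heat shock factor call ended without 093 control library 1 (adjusted p = 0.078), 093 control library 2 (0.081), 120 control library 2 (0.070) or 120 cold library 2 (0.085), and the auxin call without 093 control library 3 (0.055) or 120 control library 1 (0.052).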

How the results depend on the processing

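Of the alternatives below, the omission of 093 control library 3 together with 120 cold library 3 was chosen after seeing the data. Under the 26 alternatives run, none of the named genes and lists called changed direction. Median-ratio scaling and quantile normalization set the median change of all loci near 0, so the balance of higher and lower calls moved by construction. The share of higher calls went from 68.4% to 49.0% for the cold response in 093, from 60.0% to 49.4% in 120 and from 58.8% to 49.9% for the varieties without cold with quantile normalization. It went from 33.1% to 52.4% for the difference and from 44.4% to 57.2% for the varieties under cold with median-ratio scaling. The balance within some lists changed side under 1 or both of these scalings, in the cold response of 093 for aquaporins, class III peroxidases, flower and pollen proteins and starch synthesis and breakdown. Calvin cycle enzymes went from 3 rises and 5 falls there to 6 and 4 with quantile normalization, against the direction of the shift, and the cause was not tested. For the difference it did so for jasmonate and cytosolic ribosomal proteins, among others, and for the varieties under cold for NBS-LRR genes, among others. With no minimum change, more loci were called by construction: 10727 for the cold response in 093, 10445 in 120, 4863 for the difference, 3923 for the varieties without cold, 5218 under cold, and 8127 shared in direction by both varieties. The 19 list calls became 0 with an estimated correlation in camera, which widens the test where the estimate lies above the preset 0.01. All other counts stayed within 1.5 times the reported ones, 84 of them with settings other than omission of 1 library and 84 with it. On omission of 1 library, the counts ran from 6951 to 7312 for the cold response in 093, 6709 to 6864 in 120, 2556 to 3224 for the difference, 1417 to 1713 for the varieties without cold, 1710 to 2199 under cold, 4847 to 4963 for the shared loci and 17 to 22 for the lists. A group left with 2 libraries was assumed to vary like the other groups. Without both libraries named above, they were 7324, 6884, 3447, 1746 and 2238. Terms of both cold contrasts together numbered 235 as reported, 208 with quantile normalization and 242 with no minimum change. Those of other contrasts are not counted. With the replicate number as a block the counts were 7098, 6821, 2800, 1572 and 1854, with 4926 shared loci and 18 lists, and the numbers do not pair the libraries: residual correlations of same-numbered libraries ran from -0.08 to 0.05, with 0 of 18 pairs over 0.1. Of 195 results for named genes, 187 kept their direction and their call under every alternative, and calls of the others were lost in 11 cases with other settings and 17 with omission of 1 library. The fall of rubisco activase (Phvul.001G234300) in 093 went to -0.81 log2 with quantile normalization, under the minimum change, and the cause was not tested. The rise of no pollen germination related 2 (Phvul.007G190600) in 093 went to 0.74 with median-ratio and 0.80 with quantile scaling, under the minimum change. These scalings moved the median of all loci there by -0.41 and -0.43. The difference of PsbQ-like 2 (Phvul.003G045300) lost its call with no filter (adjusted p = 0.084), no variance trend (0.0502), the replicate block (0.053) and without both libraries named above (0.14), in a range of 0.00095 to 0.14. The rise of the MIND complex protein in 093 had an adjusted p of 0.063 without both libraries, in a range of 0.00039 to 0.063. The rise of the MLP-like protein (Phvul.009G252400) in 120 was 0.90 with median-ratio scaling and had an adjusted p of 0.099 when only the groups compared were fitted, in a range of 5.4e-05 to 0.099. No list kept its call under every alternative, 0 of 19. Beside the estimated correlation, WRKY factors lost theirs for the difference with no filter (adjusted p = 0.10) and with a filter at 5 FPKM (0.089), in a range of 0.0013 to 0.77, and auxin-responsive genes with no filter (0.55), a filter at 5 FPKM (0.19) and library weights (0.070), in a range of 0.0064 to 0.77. Heat shock transcription factors lost theirs in 120 with a pseudocount of 0.1 (0.052), no filter (0.15), TPM (0.051), library weights (0.060), a fit of only the groups compared (0.056) and the replicate block (0.0505), and for the difference with a pseudocount of 0.1 (0.075), no filter (0.10), TPM (0.10), median-ratio (0.12) and quantile scaling (0.12). Sucrose and trehalose metabolism under cold lost its call with library weights (0.054) and without both libraries named above (0.055), and auxin-responsive genes without both (0.13). The cause of these losses was not tested. Read totals are unknown, so depth limits what low loci can show by an unknown amount.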

Other observations

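Of the tests in this part, the use of the planned scaling to equal totals as a test of unequal totals and the 4 counts of called loci over splits of 3 libraries against 3 were chosen only after the results were seen.

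The 24 loci that were among the 10 highest of any library, chosen after their values were seen, took 22.2 ± 3.13% of the FPKM in 093 control, 8.38 ± 0.466% in 093 cold, 17.7 ± 0.905% in 120 control and 9.60 ± 0.649% in 120 cold. Of them 8 had no description. Photosystem II subunit R (Phvul.005G055200) went from 4549.5 ± 1298 to 1183 ± 87.0 FPKM in 093 and from 3751 ± 105 to 1052 ± 42.6 FPKM in 120. Alanine:glyoxylate aminotransferase (Phvul.006G029100), a photorespiration enzyme, went from 2005 ± 462 to 425 ± 6.79 FPKM in 093 and from 2495 ± 205 to 435 ± 24.7 FPKM in 120. A cobalamin-independent methionine synthase (Phvul.001G113800) went the other way, from 55.5 ± 17.4 to 1702 ± 81.7 FPKM in 093 and from 99.7 ± 9.98 to 905 ± 197 FPKM in 120. The undescribed locus Phvul.002G203700 varied between libraries, with 11405 ± 5451 FPKM in 093 control and 3235 ± 1737 in 120 cold.

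Some loci were detected in 1 variety in all 6 libraries at 5 FPKM or more and were listed at 0 in the other, and were chosen after their values were seen. Listed at 0 in 120 were 3 loci: the ferredoxin-like MSTRG.7297, a phosphoenolpyruvate carboxylase family gene (Phvul.003G021600) at 5.90, 5.05 and 6.97 FPKM in 093 control and 5.93, 5.41 and 6.54 FPKM in 093 cold, and the undescribed MSTRG.6276. Listed at 0 in 093 were 2 undescribed loci, MSTRG.12304 and MSTRG.5062.

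More loci were higher than lower under cold in 093. Equal totals gave 66.0% higher calls, but totals (313320 to 350100 FPKM) were too alike to test them as the cause. A candidate explanation is the share of FPKM held by a few loci in the control libraries: with the 24 highest loci left out and the rest rescaled, the median log2 change went from 0.43 to 0.19 and the share of higher calls from 68.5 to 58.4%. That median lies between the bounds of 0.1 and 0.2 set beforehand, so this and a wider rise of transcripts under cold cannot be told apart. Total RNA per leaf is not known, and a biological difference stays open and untested.

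The libraries most apart from the rest of their group were 093 control library 3 and 120 cold library 3. In them 763 and 933 loci lay at least 1 log2 from the mean of the rest of the group, against 284 to 593 in the other libraries. Mixing of RNA from the other treatment was tested with marker loci abundant in the other treatment and under 1 FPKM in the other two libraries. In 093 control library 3, 274 of the 566 higher loci were also higher in cold and would need a share of 37.3% of cold RNA, but 100% of 15 markers lay under 50% of that level, with a median of 0.354% of the cold level. In 120 cold library 3, a share of 40.0% was needed and 97.4% of 39 markers lay under 50% of it, with a median of 1.53%. These values argue against mixing at the needed share in both libraries, and a difference between plants stays open and untested.

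The 10 splits of 6 libraries into 3 against 3 are too few for a share under 0.05. For the cold response in 093 the real split called 7096 loci and the highest other 2, with 1 of 10 as large. For 120 the counts were 6825 and 1, for the varieties without cold 1586 and 2, and under cold 1861 and 2, each with 1 of 10 as large. For enriched terms the real counts were 102 in 093 and 133 in 120 and the highest others 0 and 0, again with 1 of 10 as large. For lists called, 4 of 10 splits were as large in 093 (real 5, highest other 7), 5 of 10 in 120 (8 and 13), 9 of 10 between the varieties without cold (1 and 5) and 10 of 10 under cold (1 and 6). For lists called on the difference of the responses, with variety labels redrawn within treatments, 24 of 100 splits were as large (4 and 9), so chance is not excluded. The 4926 loci called in the same direction in both varieties were reached by 1 of 100 splits with treatment labels redrawn within varieties, the real one, and the highest other was 36, which equals the number of loci called in opposite directions. Other splits of 1 variety called at most 2 loci, so this count repeats that many loci differed by treatment and does not test whether varieties agree.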
